A study of Mus musculus with 12 samples.

How the data were processed

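Bulk RNA of mouse dorsal cortex (strain C57BL/6) was measured in 12 libraries: 3 WT and 3 Ash2l cKO libraries at each of the ages E14.5 and E16.5. Groups were taken from the genotype and age in the labels. RNA was extracted with TRIzol, and libraries were made from total RNA with Illumina protocols, per the labels.

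The authors aligned read pairs with STAR 2.5.2b to mm10, per the submitters' processing notes. The deposited values are raw counts of fragments per gene, made with featureCounts 1.5.2, per the file headers. The command counts read pairs as fragments over RefSeq exons of mm10, on the reverse strand (setting 2), keeping pairs with both ends aligned, leaving out chimeric pairs and asking for an overlap of at least 25 bases, per the file headers. No option for multi-mapped or overlapping assignments appears in that command, so genes with near-identical copies, such as ribosomal proteins and haemoglobins, are less certain. Because strand was used, antisense partners were counted apart. The authors also deposited a table for each age with log2 fold changes of WT over knockout, their standard errors, p-values and adjusted p-values from DESeq2 1.14.1, per the submitters' processing notes and the file headers. The direction of that log2 ratio was read from the library columns. The design formula and the treatment of small fold changes are not given in the sources used here. The 12 columns of normalised library values in those tables were not used. The tables hold 27179 genes, of which 26332 have a symbol and 847 do not.

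Library totals ran from 14318147 to 24719047 counts. Ribosomal RNA gene Rn45s took between 2.28% and 6.11% of them. Pairs of libraries in 1 group were compared by a chi-square test of their counts, and the statistic per degree of freedom lay between 9.51 and 51.5, so no library was treated as a copy of another.

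Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and its F test, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. Each age was fitted alone on its 6 libraries with genotype as the only term. The age difference of the cKO effect and the WT age comparison used 1 fit of 12 libraries with 4 groups, which is possible because both tables hold the same genes in the same order and were counted with the same settings. Printed standard errors are the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM on TMM effective library sizes, except single-library levels of marker genes, which are CPM on library totals. Log CPM used a prior count of 2. The scripts were tested on simulated data with known changes: at a 2-fold change edgeR recovered 75.8% of changed genes at E14.5 (14611 genes), 80.3% at E16.5 (14709 genes), 53.0% for the age difference (15155 genes) and 66.7% for the WT age comparison (15164 genes). At 1.5-fold the shares were 20.6%, 47.1%, 1.47% and 29.4%.

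Before the data were examined, 32 gene lists were fixed, along with the tests, the alternatives and the rule for named genes. A list needs 3 tested members, and the clustered Hox list had 0 in every comparison, so 31 lists were tested. Lists were tested with camera, which compares a list with all other genes, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. Of the lists called with the preset correlation, the sex-linked list at E14.5 alone passed with the estimated one. The test fry asks whether the members of a list move, on balance, in 1 direction, without comparing them with other genes. At E16.5 it gave an adjusted p of 0.0293 for pan-neuronal markers and 0.0428 for deep-layer and subplate markers, both lower. With the block described below these were 0.123 and 0.223, so neither passed. At E14.5 fry gave an adjusted p of 0.0364 for astrocyte and oligodendrocyte lineage markers and 0.00258 for sex-linked genes, both lower. With the block these were 0.193 and 0.0604. No other list passed fry for 1 direction in the single-age fits without the block. Its mixed form asks whether members change in either direction, and it is given here for the Wnt lists. A list is said to pass where camera called it, unless fry is named. A list's value is the median log2 fold change of its tested members. The lists are of known markers, several genes stand in more than 1 list, and in bulk tissue they describe expression and not cell numbers.

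The rule for named genes takes Ash2l, and then called genes whose 3 cKO libraries all lie above or all below the 3 WT libraries, with a mean of at least 1 CPM and without clone, predicted or pseudogene symbols. Of these it takes the 6 largest increases and 6 largest decreases and the 5 smallest p-values in each direction. From each list it takes up to 4 called members by p, or up to 2 members as values where none is called, and up to 12 called Wnt members. For the WT age comparison it takes 5 genes in each direction. Some genes that the rule takes are not reported here. Other pan-neuronal genes in a caption, and Dlx6os1, fall outside it.

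The numbers shared in the titles were checked for pairing from the correlation of each library's deviations from its group mean. At E16.5 the same-numbered libraries correlated at 0.11 to 0.28, each over the limit of 0.1, and 6 of 6 libraries correlated best with their own number. A pair with unlike numbers also lay over that limit, at 0.107, near the lowest same-numbered value of 0.112. Deviations from a group mean sum to 0, so values above 0 for same numbers push those for other numbers below 0. On this limited ground the numbers were taken to pair the libraries at E16.5 from the data, since the labels do not say what they mean. The blocked value stands beside the call of a named gene or list where it changes that call. Counts of called list members are from the fit without the block unless the block is named. Embryo sex was read from Xist and Y-linked counts, which split the libraries without overlap.

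Alternatives were DESeq2's size factors or library totals as scaling, no low-count filter or 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the block, embryo sex, 1 fit of 12 libraries, stricter thresholds and each library left out in turn. The fits with embryo sex in 12 libraries, pairs of libraries left out, ribosomal RNA removed, the 6 WT libraries alone and all list tests of the age difference were added after the data were examined. DNA-binding data named in the design text were not used here.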

Results

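RNA from mouse embryonic dorsal cortex was sequenced in 12 libraries, at embryonic day E14.5 and at E16.5. At each age 3 libraries came from wild-type (WT) embryos and 3 from conditional knockout (cKO) embryos. In the cKO embryos a Cre recombinase under the D6 promoter, which is active in the dorsal telencephalon, removes Ash2l. Ash2l encodes a core subunit of the COMPASS complexes, which methylate histone H3 at lysine 4. The series asks what Ash2l does while the cortex forms, and its title points to Wnt signalling, the secreted-ligand pathway that acts through beta-catenin. The libraries hold between 14318147 and 24719047 counted fragments over 27179 genes. The titles give each age 3 numbers, each shared by 1 WT and 1 cKO library. Libraries are named here by genotype and by the letters A, B and C, in ascending order of that number within each age, so that WT A and cKO A share a number. Each title also holds a second number, and no library shares both numbers with another. The labels used here do not say what the numbers stand for, so the p-values measure the spread between these libraries, which may in part be technical. Values are CPM (a gene's share of the counts of its library, scaled to a common total) as mean ± SD over 3 libraries, and changes are log2 fold changes of cKO over WT with their standard error (SE).

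The targeted gene, Ash2l (Entrez 23808), lies on the minus strand of chromosome 8 from 25816870 to 25847670 in mm10 and has 17 exons there. At E14.5 its level was 128 ± 13.3 CPM in WT (SD, n = 3) and 52.8 ± 5.99 CPM in cKO (SD, n = 3). The log2 fold change was -1.28 (SE 0.121, edgeR adjusted p = 0.0124). At E16.5 it was 134 ± 3.36 CPM in WT and 58.2 ± 3.29 CPM in cKO (SD, n = 3 each), a change of -1.20 (SE 0.0683, adjusted p = 8.19e-04). All 6 cKO libraries lay below all 6 WT libraries, so no label goes against its Ash2l level. The counts cover all exons of the gene. The labels do not say which exons are deleted, so fragments from exons left after recombination, or from cells that the Cre does not reach, still count. At E14.5 the call was lost without WT C (adjusted p = 0.0885) and without cKO C (adjusted p = 0.108), while the log2 fold changes were -1.34 and -1.26.

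**Figure D1:**
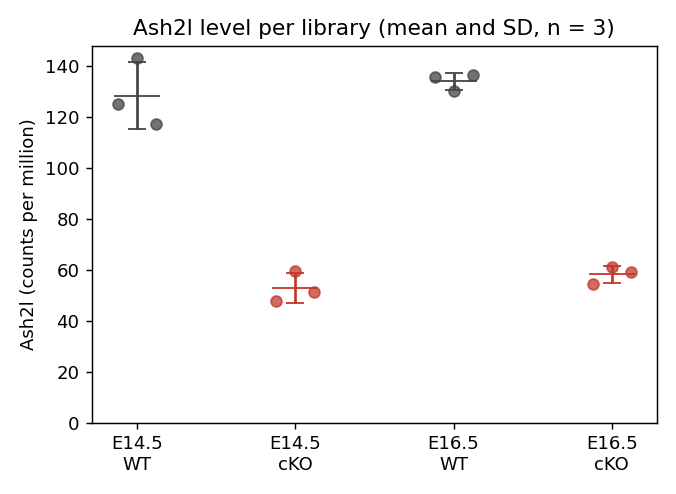
Ash2l in each of the 12 libraries, as CPM on a linear axis from 0, by age and genotype. Points are libraries and the bar with whiskers is the mean and SD of 3 libraries. The means are 128 (WT) and 52.8 (cKO) at E14.5, and 134 and 58.2 at E16.5.

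The first comparison asks what the loss of Ash2l changes at E14.5. Of 14788 genes tested, 297 passed an adjusted p of 0.05, of which 52 were higher and 245 lower in cKO. Outside the X and Y chromosomes the count was 281, with 47 higher and 234 lower. Cbln2, a secreted synaptic organiser, changed by -2.85 (SE 0.395, adjusted p = 0.0258) and Ankrd63 by -2.41 (SE 0.399, adjusted p = 0.0375). Several of the largest increases began from low levels. Agbl1, a deglutamylase of tubulin, was 3.11 ± 0.677 CPM in WT and 11.2 ± 0.459 CPM in cKO (log2 fold change 1.85, SE 0.198, adjusted p = 0.0130). Casq1, a calcium-binding protein of muscle, changed by 1.47 (adjusted p = 0.0130), Pou2af1, a transcriptional coactivator of B cells, by 2.35 (adjusted p = 0.0436), and Cacna1s, a calcium channel of skeletal muscle, by 2.23 (adjusted p = 0.0258). Zbbx changed by 2.04 (adjusted p = 0.0444). Pipox, which oxidises pipecolic acid, and Slc14a2, a urea transporter, each changed by 1.21 (adjusted p = 0.0179 and 0.0207).

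At E14.5 the WT and cKO libraries also differed in embryo sex, so the E14.5 libraries alone do not separate sex from genotype. The 3 WT libraries carried Y-linked transcripts and the 3 cKO libraries carried Xist, the RNA that silences 1 X chromosome in females. Xist was 3.04 ± 3.04 CPM in WT and 3358 ± 382 CPM in cKO (log2 fold change 10.05, adjusted p = 0.00271). The Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty had log2 fold changes from -10.71 to -8.57. The sex-linked list, with 5 members tested, therefore passed its test (adjusted p = 2.80e-82, and adjusted p = 0.0193 with an estimated correlation). Of the 297 genes, 12 were on X and 4 on Y. With all 12 libraries in 1 fit with sex as a term, added after the data were examined, 128 genes passed (24 higher and 104 lower), against 1336 in the same fit without sex, while Ash2l was at -1.33 with sex and -1.29 without it. Sex and genotype coincide at E14.5, so the sex term in that fit rests on the E16.5 libraries alone. Its error adds to that of each E14.5 change, so a lost call need not mean a smaller change. Of 24 named called genes besides Ash2l, 12 kept direction and call with sex and 22 without it. Those that missed the threshold with sex included Xist, Eif2s3y, Kdm5d, Ddx3y and Uty. Embryo sex was read from these same genes, so their loss under a sex term was fixed in advance. Others were Pou2af1 (2.73, adjusted p = 0.0871), Nefm (-2.26, adjusted p = 0.0864), Sstr2 (-0.77, adjusted p = 0.140) and Ddit4l (-1.36, adjusted p = 0.225). In the E14.5 fit alone Pou2af1 was at 2.35, Nefm at -1.74, Sstr2 at -0.70 and Ddit4l at -1.79. For the 281 genes outside X and Y, the sex coefficient at E16.5, where both genotypes held both sexes, had a median ratio of -0.0713 to the E14.5 change, and the genotype effect at E16.5 one of 0.980.

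Calls at E14.5 also rested on single libraries. Without WT C or without cKO C, 5 genes passed. Without WT B or without cKO B the count was 41, without WT A it was 66, and without cKO A there were 56 higher and 298 lower genes. In all 297 genes the 3 cKO libraries lay on 1 side of the 3 WT libraries, which chance gives for 10% of genes and which held for 27.3% of all genes tested. Leaving out WT B and cKO A together, a choice made after the data were examined, gave 621 genes.

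At E14.5 the pan-neuronal list passed its test with the preset correlation and not with an estimated one. The 20 markers had a median log2 fold change of -0.54 (camera adjusted p = 2.44e-07, and adjusted p = 0.863 with an estimated correlation). Over all genes tested 1 member, Nefm, a neurofilament subunit, passed (-1.74, SE 0.309, adjusted p = 0.0407), and 8 were lower when adjusted over the list alone. Relative to the WT mean the list stood at -0.99 in cKO A, -0.28 in cKO B and -0.34 in cKO C, and its median was -0.36 without cKO A (adjusted p = 0.00104). In cKO A meningeal markers (2.98), red blood cell markers (1.47) and endothelial and pericyte markers (0.74) also stood above the WT mean. The upper-layer neuron list had a median of -0.38 (adjusted p = 0.109) and the deep-layer and subplate list one of -0.26 (adjusted p = 0.126), with 0 of 14 members called in each. Cux2, for example, was at -1.06 (adjusted p = 0.137) and Bcl11b at -0.55 (adjusted p = 0.157). Among progenitor genes, Hopx, a homeodomain protein of radial glia, rose by 0.97 (SE 0.157, adjusted p = 0.0355). It was the only call among 20 apical progenitor markers (list median 0.24, adjusted p = 0.181). Sstr2, a somatostatin receptor, fell by 0.70 on the log2 scale (adjusted p = 0.0410), as 1 of 14 intermediate progenitor markers (median -0.09, adjusted p = 0.139). Some of these lists passed with 1 library left out: upper-layer markers without WT A (-0.49), WT C (-0.43) or cKO C (-0.39), deep-layer markers without cKO C (-0.33), and intermediate progenitor markers without cKO A (-0.24), WT B (-0.18) or cKO C (-0.15). Other fits moved them towards 0 or past it: upper-layer markers were at -0.16 without WT B and -0.22 without cKO A, and deep-layer markers at -0.16 without cKO A. Intermediate progenitor markers were at -0.02 without WT A and 0.05 without cKO B, and apical progenitor markers at 0.10 without WT B and 0.13 without cKO A. Cux2 was at -0.66 without WT B.

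The 28 G1/S genes of the cell cycle had a median of 0.23 at E14.5 (adjusted p = 0.0295, and adjusted p = 0.863 with an estimated correlation), with 0 members called. That call was lost without WT B (adjusted p = 0.182), and without cKO A the median was -0.02 (adjusted p = 0.988). The 24 G2/M genes had a median of 0.23 (adjusted p = 0.0996) and passed without WT A (0.33), cKO B (0.35) or cKO C (0.29), while their median was 0.12 without WT B (adjusted p = 0.386) and -0.02 without cKO A (adjusted p = 0.854). The 79 cytosolic ribosomal protein genes had a median of 0.18 (adjusted p = 2.44e-07, and adjusted p = 0.863 with an estimated correlation), also with 0 members called. In the COMPASS list of 22 genes (median 0.08, adjusted p = 0.460, and 0.02 without cKO C), Ash2l was lower and Kdm6a was higher (0.72, SE 0.104, adjusted p = 0.0264). Kdm6a is an X-linked histone demethylase, and with sex as a term in the 12-library fit its change was 0.27 (adjusted p = 0.629).

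In the 4 Wnt lists 1 gene was called at E14.5. Fzd7, a receptor for Wnt ligands, was 25.5 ± 2.05 CPM in WT and 13.2 ± 0.403 CPM in cKO (log2 fold change -0.95, SE 0.109, adjusted p = 0.0156). With sex as a term in the 12-library fit it was at -0.93 (adjusted p = 0.144), and at -0.96 in that fit without sex, where it passed. The list of ligands, receptors and secretion genes had a median of -0.02 over 31 genes (adjusted p = 0.464), and signal transduction one of -0.04 over 23 genes (adjusted p = 0.414). The beta-catenin feedback targets had a median of -0.10 over 12 genes (adjusted p = 0.650), and the secreted inhibitors one of -0.17 over 11 genes (adjusted p = 0.813). With 1 library left out these medians ran from -0.12 (WT B) to 0.01 (WT C) for ligands, receptors and secretion and from -0.13 (cKO A) to 0.01 (cKO B) for signal transduction. They ran from -0.23 (WT B) to 0.03 (cKO B) for feedback targets and from -0.20 (WT B) to -0.02 (WT C) for inhibitors, and none passed. Adjusted over the list alone, 1 inhibitor was higher and 1 lower, while over all genes Cer1 was at 2.01 (adjusted p = 0.0934) and Sfrp2 at -0.80 (adjusted p = 0.0806). By the mixed form of fry, ligands, receptors and secretion (adjusted p = 0.00125) and inhibitors (adjusted p = 0.00178) passed. Signal transduction (adjusted p = 0.109) and feedback targets (adjusted p = 0.538) did not.

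Other signalling and stress lists did not pass at E14.5. The BMP list had a median of -0.12 over 20 genes (adjusted p = 0.373), with Chrd, the secreted BMP antagonist chordin, lower by -1.38 (SE 0.185, adjusted p = 0.0226). The Notch list had a median of 0.02 (adjusted p = 0.590) and the Hedgehog list one of 0.17 (adjusted p = 0.848), where Ptch1 was at -1.02 (adjusted p = 0.0790). The p53 target list had a median of 0.07 (adjusted p = 0.590), with Ddit4l lower by -1.79 (adjusted p = 0.0258). The integrated stress response list had a median of 0.11 (adjusted p = 0.460) and the hypoxia and glycolysis list one of 0.10 (adjusted p = 0.650), with Pfkp, a phosphofructokinase, lower by -1.36 (adjusted p = 0.0452). The Notch list passed without cKO B (0.15, adjusted p = 0.0340) and the hypoxia and glycolysis list without WT C (0.34, adjusted p = 0.00839). Without cKO A the medians were -0.13 for Notch, -0.30 for BMP, -0.01 for Hedgehog, 0.00 for p53 targets, -0.03 for the integrated stress response and 0.03 for hypoxia and glycolysis. Without WT B the Hedgehog median was -0.00 and that of hypoxia and glycolysis -0.04.

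Markers of neighbouring tissue varied between E14.5 libraries. The 21 GABAergic and ventral telencephalon markers had a median of -1.28 (adjusted p = 2.58e-04, and adjusted p = 0.863 with an estimated correlation), with 0 members called and a median of -0.58 without WT B (adjusted p = 0.0266). Dlx2, a ventral transcription factor, was 34.6 CPM in WT B and 1.05 CPM in cKO A. Choroid plexus markers had a median of -1.69 (adjusted p = 0.123), which was -0.04 without WT A, where Ttr, the transthyretin gene, reached 426 CPM. Meningeal fibroblast markers had a median of 1.33 (adjusted p = 0.145), which was 0.04 without cKO A, where Col1a1 reached 62.5 CPM. Red blood cell markers were at 0.69 (adjusted p = 0.123), microglia and immune markers at 0.26 (adjusted p = 0.139), and endothelial and pericyte markers at 0.09 (adjusted p = 0.813). Cajal-Retzius markers were at 0.05 (adjusted p = 0.848), hippocampal and cortical hem markers at -0.13 (adjusted p = 0.531), and astrocyte and oligodendrocyte lineage markers at -0.23 (adjusted p = 0.161). By fry the astrocyte and oligodendrocyte list passed (adjusted p = 0.0364), though not with the block (adjusted p = 0.193). Immediate early genes were at -0.20 (adjusted p = 0.730) and mitochondrially encoded genes at 0.20 (adjusted p = 0.135). With 1 library left out, calls appeared for choroid plexus markers without WT B (-2.05) or WT C (-2.05), and for meningeal markers without cKO B (1.87), WT C (2.23) or cKO C (1.66). They also appeared for red blood cell markers without WT B (0.84), cKO B (0.79) or cKO C (0.87), and for microglia and immune markers without WT B (0.44) or cKO C (0.44). Without cKO A, however, the medians were 0.09 for red blood cell markers (adjusted p = 0.870), -0.02 for microglia and immune markers and -0.42 for endothelial and pericyte markers, and without WT A they were 0.35, 0.07 and -0.00. Astrocyte and oligodendrocyte lineage markers passed without WT A (-0.51) and were at -0.11 without WT B and -0.53 without cKO A. Mitochondrially encoded genes passed without cKO A (0.30) or WT C (0.42) and were at 0.04 without WT B and 0.07 without cKO B. Without cKO B Cajal-Retzius markers were at -0.22, hippocampal and hem markers at -0.28 and immediate early genes at -0.08. The mitochondrial ribosomal RNA Rnr2 was 109 CPM in WT B and between 2436 and 3622 CPM in the other E14.5 libraries.

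The second comparison asks the same question at E16.5. Of 14865 genes tested, 2358 passed (15.9%), with 889 higher and 1469 lower in cKO. A block for the shared number, which was taken to pair the libraries at this age, gave 4790 genes (2132 higher and 2658 lower). With library totals alone as the scaling 1163 were higher and 1328 lower, so the excess of lower genes was smaller with that scaling. Gucy1b2, a guanylate cyclase subunit, was 4.88 ± 0.187 CPM in WT and 27.9 ± 2.16 CPM in cKO (log2 fold change 2.52, SE 0.113, adjusted p = 2.97e-04). Elovl2, an elongase of very long fatty acids, was 83.8 ± 7.41 CPM in WT and 27.5 ± 2.85 CPM in cKO (log2 fold change -1.61, SE 0.103, adjusted p = 8.19e-04). Fbn2, an extracellular fibrillin, changed by -1.91 (SE 0.126), Ptpn5, a phosphatase of neurons, by -1.71 (SE 0.110), and Smoc1, a secreted calcium-binding protein, by -1.49 (SE 0.0988), each at an adjusted p of 8.19e-04. Leaving out clone and predicted symbols and genes with a mean under 1 CPM, the largest decreases were in Ccdc109b (-2.66), the potassium channel subunit Kcng3 (-2.50), the adrenergic receptor Adra2c (-2.50), the ATP-gated channel P2rx2 (-2.46), the transporter Abca4 (-2.26) and Zdhhc23 (-2.23), with adjusted p between 0.00275 and 0.0126.

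With the same symbols and levels left out, the largest increases at E16.5 were in genes with little RNA in WT. Pou2af1 was 0.0890 ± 0.0574 CPM in WT and 3.31 ± 1.02 CPM in cKO (log2 fold change 5.09, SE 0.476, adjusted p = 0.00173). The others were Kank4os (4.20), the neuropeptide receptor Npsr1 (4.11), Arhgap15 (3.48), the lipoprotein gene Apob (3.39) and the deiodinase Iyd (2.97), with adjusted p between 0.00181 and 0.0153. Among the smallest p-values were Casq1 (2.0, adjusted p = 0.00126), Arhgap26 (1.35, adjusted p = 0.00157) and Vps13b (0.59, adjusted p = 0.00181). Of the 889 higher genes, 109 had a WT mean under 1 CPM. At least a 2-fold change held for 669 genes, of which 191 were higher and 478 lower.

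Of 20 pan-neuronal markers at E16.5, 13 were lower and 0 higher over all genes tested, and 15 were lower when adjusted over the list alone. With the block, where 4790 of 14865 genes passed, 18 were lower and 1 higher. The list median was -0.50 (camera adjusted p = 2.45e-07, and adjusted p = 0.568 with an estimated correlation), and each library left out in turn gave a median between -0.55 and -0.44 that passed. Stmn2, a regulator of microtubules in growing axons, was 527 ± 40.7 CPM in WT and 214 ± 18.4 CPM in cKO (log2 fold change -1.30, SE 0.0886, adjusted p = 8.19e-04). Tubb3, the neuronal beta-tubulin, was 1078 ± 106 CPM in WT and 746 ± 56.6 CPM in cKO (log2 fold change -0.53, adjusted p = 0.00898). Slc17a7, a vesicular glutamate transporter, changed by -0.73 (adjusted p = 0.0107) and Gap43, a growth cone protein, by -0.48 (adjusted p = 0.00498).

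**Figure D2:**
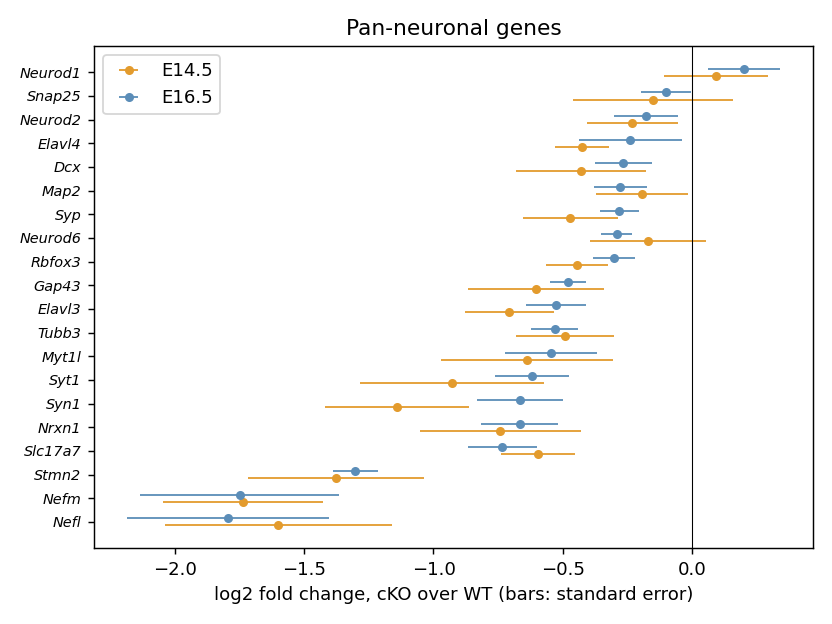
Log2 fold change of cKO over WT for the 20 pan-neuronal genes at E14.5 and at E16.5, with horizontal bars for the standard error and genes ordered by the E16.5 value. At E16.5 the values run from -1.80 (Nefl) to 0.20 (Neurod1), and the list median is -0.50.

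Layer markers at E16.5 fell in part, while 15.9% of all genes tested were called. Of 14 upper-layer markers 2 were lower, Unc5d, a netrin receptor (-0.50, SE 0.0689, adjusted p = 0.00403), and Pou3f1 (-1.09, SE 0.267, adjusted p = 0.0309). Their list median of -0.35 did not pass (adjusted p = 0.0664). With the block it was -0.37 and passed (adjusted p = 4.97e-05, and adjusted p = 0.840 with an estimated correlation). In that fit, where 4790 of 14865 genes passed, 10 upper-layer markers were lower and 1 higher. Of 14 deep-layer and subplate markers 4 were lower, Tle4 (-0.57), Lmo3 (-0.50), Ldb2 (-0.55) and Fezf2 (-0.24), with adjusted p between 0.00701 and 0.0446. The list did not pass camera (median -0.15, adjusted p = 0.183). It passed fry (adjusted p = 0.0428), though not with the block (adjusted p = 0.223). With embryo sex as a covariate Pou3f1 (-1.04, adjusted p = 0.0606), Ldb2 (-0.56, adjusted p = 0.0784) and Fezf2 (-0.24, adjusted p = 0.0870) missed the threshold. The upper-layer list also passed without cKO A (-0.50), WT B (-0.40) or WT C (-0.41).

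Progenitor and G2/M genes went both ways at E16.5, while the G1/S genes called were higher. Over all genes tested 15.9% were called. Among 20 apical progenitor markers Hopx (0.82, adjusted p = 0.00976) and Hes5 (0.68, adjusted p = 0.0412) were among 3 higher, while Mfge8 (-0.36, adjusted p = 0.0185) and Ptprz1 (-0.37, adjusted p = 0.0231) were lower, and the list median was 0.19 (adjusted p = 0.412). Of 14 intermediate progenitor markers Sstr2 (-0.72, adjusted p = 0.0182) and Coro1c (-0.31, adjusted p = 0.0218) were lower (list median -0.05, adjusted p = 0.602). Of 28 G1/S genes 4 were higher and 0 lower: Rfc2 (0.37), Ccne1 (0.77), Cdk2 (0.51) and Prim1 (0.41), with adjusted p between 0.0117 and 0.0492. Of 24 G2/M genes Cdca8 was higher (0.44, adjusted p = 0.0371) and Plk1, a mitotic kinase, lower (-0.77, adjusted p = 0.0397). The G1/S median of 0.23 (adjusted p = 0.0711) and the G2/M median of 0.24 (adjusted p = 0.243) did not pass. With the block they were 0.22 (adjusted p = 0.0227) and 0.23 (adjusted p = 0.0248), each with an adjusted p of 0.914 with an estimated correlation. In that fit, where 4790 of 14865 genes passed, 13 G1/S genes were higher and 0 lower. It also gave 13 G2/M genes higher and 3 lower, and 9 apical progenitor markers higher and 4 lower. With 1 library left out, G1/S genes passed without cKO A (0.33) or WT C (0.33), G2/M genes without cKO A (0.42) and apical progenitor markers without cKO A (0.30). Without cKO C the medians were 0.10 for G1/S, 0.07 for G2/M (adjusted p = 0.958) and 0.10 for apical progenitor markers, and without WT A they were 0.16, 0.13 and 0.11. The intermediate progenitor median ran from -0.23 (without cKO C) to 0.11 (without cKO A). With embryo sex as a covariate Hes5 (0.68, adjusted p = 0.0694), Coro1c (-0.31, adjusted p = 0.0530), Cdk2 (0.51, adjusted p = 0.0866), Prim1 (0.40, adjusted p = 0.0867) and Cdca8 (0.43, adjusted p = 0.0737) missed the threshold.

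No Wnt list passed camera, or fry for 1 direction, at E16.5, while single members were called. By the mixed form of fry all 4 passed (adjusted p = 0.00121 for ligands, receptors and secretion, and 0.00110 for each other list). That form does not set a list against other genes, and the BMP list passed it too (adjusted p = 1.54e-05). Over the 4 lists 13 of 76 genes tested were called (17.1%), beside 15.9% of all genes tested, and at E14.5 it was 1 of 75, beside 2.01%. Among 34 ligand, receptor and secretion genes 4 were lower and 0 higher (median -0.11, adjusted p = 0.357). They were the receptors Fzd7 (31.7 ± 4.59 CPM in WT and 12.8 ± 3.69 CPM in cKO, log2 fold change -1.30, SE 0.212, adjusted p = 0.00711) and Fzd6 (-0.57, adjusted p = 0.0401), the R-spondin receptor Lgr4 (-1.04, SE 0.154, adjusted p = 0.00513) and the ligand Wnt5b (-1.48, adjusted p = 0.0222). Of 23 signal transduction genes 4 were lower and 1 higher (median -0.04, adjusted p = 0.423), and adjusted over the list alone 6 were lower and 1 higher. With the block, where 4790 of 14865 genes passed, 9 signal transduction genes were lower and 2 higher. In that fit 7 ligand, receptor and secretion genes were lower and 1 higher. Pygo1, a coactivator of beta-catenin, changed by -0.70 (adjusted p = 0.00665), the corepressors Tle4 by -0.57 (adjusted p = 0.00701) and Tle1 by 0.23 (adjusted p = 0.0375), the transcription factor Tcf7 by -0.80 (adjusted p = 0.0390) and the kinase Csnk1a1 by -0.32 (adjusted p = 0.0413). Of 13 feedback targets, Tcf7 and Nkd2, an inhibitor of Dishevelled, were lower (Nkd2 -1.47, SE 0.174, adjusted p = 0.00264) and Apcdd1 was higher (0.36, adjusted p = 0.0473), with a list median of -0.11 (adjusted p = 0.512). Of 9 genes in the list of secreted inhibitors Kremen1, a membrane protein that is not itself secreted, was higher (0.62, adjusted p = 0.0113). Draxin was lower (-0.46, adjusted p = 0.0158), and the list median was -0.11 (adjusted p = 0.927). With 1 library left out the median of ligands, receptors and secretion ran from -0.18 (cKO B) to -0.04 (cKO A), that of signal transduction from -0.08 (cKO C) to -0.04 (WT C), that of feedback targets from -0.17 (cKO A) to -0.10 (WT C) and that of inhibitors from -0.22 (cKO C) to 0.07 (WT B). With embryo sex as a covariate Fzd6 (-0.57, adjusted p = 0.0757), Tle1 (0.23, adjusted p = 0.0833), Tcf7 (-0.80, adjusted p = 0.0720) and Csnk1a1 (-0.32, adjusted p = 0.0794) missed the threshold.

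In other signalling lists at E16.5, members of the Notch, BMP and Hedgehog pathways were called without the lists passing. These calls stand beside 15.9% of all genes tested, so they do not set the lists apart. Of 22 Notch genes the ligand Jag2 (-1.02, adjusted p = 0.00916) and Dtx4 (-0.46, adjusted p = 0.0220) were lower, and Maml3 (0.30, adjusted p = 0.0355) and Hes5 were higher, with a list median of 0.13 (adjusted p = 0.430). With the block, where 4790 of 14865 genes passed, 7 Notch genes were higher and 2 lower. Of 19 BMP genes Chrd (-1.36, SE 0.154, adjusted p = 0.00221) and Smad1 (-0.27, adjusted p = 0.0243) were lower (median -0.24, adjusted p = 0.357, and -0.06 without WT C). Ptch1, the Hedgehog receptor, was lower (-0.60, adjusted p = 0.0260), while its list of 11 had a median of 0.07, a mean of -0.07 and a test directed down (adjusted p = 0.963). Without cKO C the Hedgehog median was -0.06 and without cKO A 0.20. Of 22 COMPASS genes the subunits Rbbp5 (0.28, SE 0.0616, adjusted p = 0.0220) and Cxxc1 (0.26, SE 0.0739, adjusted p = 0.0479) were higher and Ash2l lower (list median 0.11, adjusted p = 0.577). With embryo sex as a covariate Rbbp5 (0.28, adjusted p = 0.0513), Cxxc1 (0.26, adjusted p = 0.0926), Smad1 (-0.27, adjusted p = 0.0521) and Maml3 (0.30, adjusted p = 0.0733) missed the threshold.

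Stress and metabolic genes at E16.5 rose in part, while 15.9% of all genes tested were called in either direction. Of 24 p53 target genes 6 were higher and 1 lower over all genes, and 8 were higher and 1 lower when adjusted over the list alone. Eda2r, a receptor of the TNF receptor family, changed by 1.34 (SE 0.243, adjusted p = 0.0103), Polk, a translesion polymerase, by 0.67 (adjusted p = 0.0167) and Ccng1 by 0.55 (adjusted p = 0.0188), while Plk2 changed by -0.80 (adjusted p = 0.0204). The list did not pass (median 0.34, adjusted p = 0.0664), but it did without cKO B (0.41), WT C (0.43) or cKO C (0.38), and without WT B the median was 0.21. Of 17 hypoxia and glycolysis genes 5 were higher, among them Pfkl (0.58, adjusted p = 0.00275), Pdk1 (0.39, adjusted p = 0.00813) and Eno1 (0.38, adjusted p = 0.0128), and Pfkp was lower (-1.45, adjusted p = 0.00257), with a list median of 0.26 (adjusted p = 0.0795), which passed without cKO A (0.25) or WT C (0.27) and was 0.11 without cKO B. Of 14 integrated stress response genes 3 were higher, Mthfd2 (0.59, adjusted p = 0.0154), Shmt2 (0.29, adjusted p = 0.0260) and Sesn2 (0.95, adjusted p = 0.0275), with a list median of 0.05 (adjusted p = 0.430, and -0.01 without WT A). Of 79 ribosomal protein genes Rps27l, which is also a p53 target, was higher (0.45, adjusted p = 0.0234), and the list median was 0.05 (adjusted p = 0.243). With embryo sex as a covariate Shmt2 (0.28, adjusted p = 0.0516) and Sesn2 (0.95, adjusted p = 0.0527) missed the threshold.

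No marker list of another cell type passed at E16.5. Choroid plexus markers had a median of -1.85 (adjusted p = 0.436), which was 0.39 without WT C, where Ttr reached 574 CPM, and which passed without WT A (-2.52). GABAergic and ventral markers were at -0.13 (adjusted p = 0.430) and passed without cKO A (-0.36, and -0.05 without cKO C), meningeal fibroblast markers at -0.22 (adjusted p = 0.423), red blood cell markers at -0.20 (adjusted p = 0.657) and microglia and immune markers at 0.27 (adjusted p = 0.436). Endothelial and pericyte markers were at -0.06 (adjusted p = 0.954), astrocyte and oligodendrocyte lineage markers at -0.20 (adjusted p = 0.467), and hippocampal and cortical hem markers at -0.10 (mean 0.01, adjusted p = 0.954). Cajal-Retzius markers were at 0.11 (adjusted p = 0.430), with 1 of 10 members, Ebf3, higher (0.45, adjusted p = 0.0290). Immediate early genes were at -0.12, with a test directed up (adjusted p = 0.954), mitochondrially encoded genes at 0.05 (adjusted p = 0.705) and sex-linked genes at -0.10, with a test directed up (adjusted p = 0.954). Several of these medians changed sign or moved with 1 library left out: microglia and immune markers were at -0.08 without cKO A, endothelial and pericyte markers at 0.08 without cKO C, hippocampal and hem markers at 0.19 without cKO A, mitochondrially encoded genes at -0.15 without WT A, and red blood cell markers ran from -0.47 (without cKO A) to 0.00 (without cKO B). Genes named from these lists that did not pass without the block but passed with it included Maf (-0.34, adjusted p = 0.0446), Igfbp2 (-0.33, adjusted p = 0.0135), Zbtb20 (-0.35, adjusted p = 0.00154), Cspg5 (-0.31, adjusted p = 0.0169), Jun (0.55, adjusted p = 0.00117) and Arc (0.74, adjusted p = 0.0305). Jun also passed without the block in DESeq2 (0.53, adjusted p = 0.0212), without cKO A (0.65) and without WT C (0.75).

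At E16.5 each genotype held 1 female and 2 male libraries by Xist and Y-linked counts. With sex as a covariate 1618 genes passed, of which 514 were higher and 1104 lower. The 18 named genes that missed the threshold with it kept their direction. The count was 987 without WT B, 995 without cKO B and 1127 without WT A. The other libraries left out 1 at a time gave counts within 1.5 times of 2358. Without WT C and cKO C together, chosen after the data were examined, it was 1223.

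The third comparison asks whether the effect of Ash2l loss differed between the ages. In the 12-library fit, 0 of 15338 genes passed the interaction test in edgeR, with 318 at an unadjusted p under 0.05 where chance gives 767, and DESeq2 also gave 0 (367 at an unadjusted p under 0.05). With the block for the shared number 1 gene passed, Dlx6os1, a ventral long noncoding RNA (1.58, SE 0.144, adjusted p = 0.0116). It was named after its value was seen and belongs to the GABAergic and ventral list. In the fit without the block it was at 1.54 (SE 0.740, adjusted p = 1.0). The greater count of called genes at E16.5 is therefore not shown to be a greater effect.

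The genes called at each age overlapped. Of 14514 genes tested at both ages 261 were called at both, of which 44 were higher at both ages (3.08 expected for independent lists, Fisher's exact test across genes p = 1.75e-46) and 217 lower at both (24.4 expected, p = 4.28e-189). None of them changed in opposite directions (0 genes), while 36 were called only at E14.5 and 2047 only at E16.5. Genes are not independent replicates, so these p-values describe the lists. The ages share no library. Of the 281 genes called at E14.5 outside X and Y, 279 (99.3%) had the same direction at E16.5, against 82.1% of all genes. Across all genes the fold changes had a Pearson correlation of 0.717 and a Spearman rank correlation of 0.769. Named genes called at both ages included Ash2l, Pou2af1, Casq1, Agbl1, Cacna1s, Ankrd63, Gucy1b2, Elovl2, Ptpn5, Fzd7, Chrd, Hopx, Sstr2, Nefm and Pfkp. The overlap was 0 without WT C or without cKO C of E14.5, 33 without WT B, 35 without cKO B and 55 without WT A. A block at both ages gave 1154 shared genes.

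**Figure D3:**
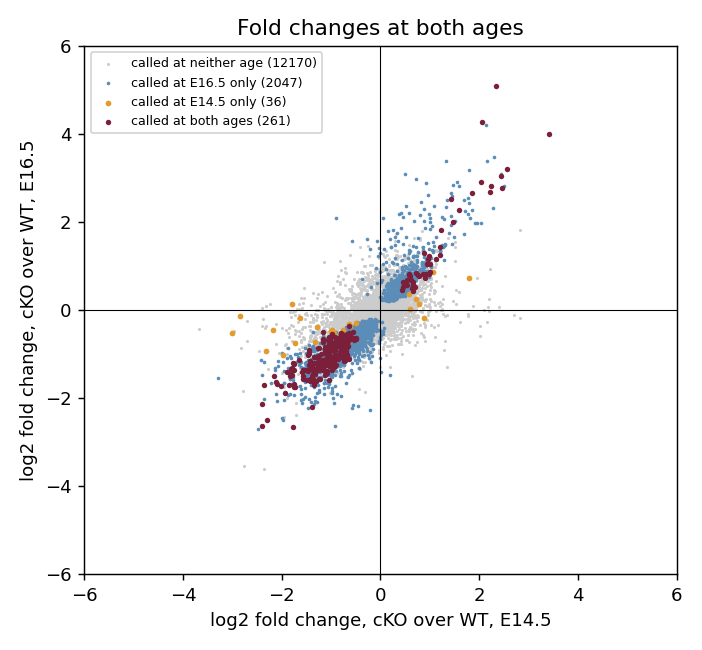
Log2 fold change of cKO over WT at E14.5 (horizontal) and at E16.5 (vertical) for 14514 genes, coloured by the age at which a gene was called. The 261 genes called at both ages lie in the lower left or upper right, and 5 genes lie outside the axes, which end at 6.

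The fourth comparison describes WT cortex between the ages, as background on normal development. Of 15338 genes 330 passed, 117 higher and 213 lower at E16.5 than at E14.5. With DESeq2's size factors as the scaling the split was 121 higher and 142 lower. Each age has its own count table, so age and any batch between the tables cannot be told apart. Gfap, an intermediate filament of astrocytes, changed by 2.5 (SE 0.492, adjusted p = 0.0353), Jakmip3 by 2.42, the desmosomal cadherin Dsg2 by 2.41 and the neuropeptide Grp by 2.30, with adjusted p between 0.0231 and 0.0481 for the last 3. Lower at E16.5 were Rnr2 (-5.13), the zinc finger gene Zfp503 (-2.78), the kinase Prkg2 (-2.52), the mitochondrial gene COX3 (-2.22) and Fign (-2.07), with adjusted p between 0.0302 and 0.0408. WT B of E14.5 stood apart in several of these: Zfp503 was 9.61 CPM there and 1.80 and 4.06 CPM in WT A and WT C, and without WT B its change was -1.97. Rnr2 was 111 CPM there against 2455 and 3233 CPM, and COX3 5.57 against 20.7 and 24.6 CPM. The calls of these 9 genes were lost without WT C of E14.5 and without WT A or WT B of E16.5, and several also without other libraries. Rnr2 also missed the threshold in the 6 WT libraries alone (adjusted p = 0.0812).

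Of the lists compared between the WT ages 11 passed with the preset correlation, and with an estimated one none of these passed (adjusted p between 0.486 and 0.615). G2/M genes had a median of -0.83 (8 of 24 called lower, 24 when adjusted over the list alone, list adjusted p = 2.94e-18) and G1/S genes one of -0.56 (1 of 28 called, 26 when adjusted over the list alone, list adjusted p = 1.83e-12). Intermediate progenitor markers were at -0.63 (adjusted p = 4.82e-07), Notch genes at -0.53 (adjusted p = 4.82e-07), apical progenitor markers at -0.42 (adjusted p = 0.00273) and hypoxia and glycolysis genes at -0.48 (adjusted p = 8.59e-05). Mitochondrially encoded genes were at -1.0 (adjusted p = 4.82e-07), integrated stress response genes at -0.30 (adjusted p = 0.0214) and ribosomal protein genes at -0.16 (adjusted p = 5.20e-06). Upper-layer markers were higher, at 0.51 (adjusted p = 0.00114), as were pan-neuronal markers, at 0.35 (adjusted p = 0.00809). The count of 330 genes was 1 without WT C of E14.5 and without WT A or WT B of E16.5, 14 without WT A of E14.5, 60 without WT C of E16.5 and 2216 without WT B of E14.5. It also moved with cKO libraries, which share the estimate of spread: it was 1813, 1280 and 55 without cKO A, B and C of E14.5, and 548 and 55 without cKO A and B of E16.5.

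The authors' deposited table for E14.5 lists 1183 genes with an adjusted p under 0.05, of which 252 were higher and 931 lower in the knockout, and it holds all 297 genes called here. These 297 were 25.1% of the authors' genes, and DESeq2 1.42.0 called 1187 genes from the same counts. The authors' deposited table for E16.5 lists 2754 (1013 higher and 1741 lower), and 2310 of the 2358 genes called here are among them. All shared genes had the same direction, once the sign of the tables, which give WT over knockout, was turned. Across genes the fold changes had a Spearman rank correlation of 0.992 at E14.5 and 0.994 at E16.5. For Ash2l the authors' deposited tables give a log2 fold change of WT over knockout of 1.21 (adjusted p = 2.21e-15) at E14.5 and 1.18 (adjusted p = 3.26e-37) at E16.5.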

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

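All list tests of the age difference in this part, and the tests of the GABAergic pattern, were chosen after the data were examined. Each of 7 lists showed a difference between the cKO effect at E16.5 and that at E14.5 by camera on the interaction term, and none of the 7 passed with an estimated correlation. Of 100 draws from 200 relabellings of genotype within each age, the real one included, 94 called as many lists (7 real, 20 the highest other, median 11 of the others), so chance is not excluded for the list calls. The other draws still carry part of the genotype effect, so they are not draws without any effect.

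The GABAergic and ventral telencephalon markers differed by 1.17 (median log2 fold change at E16.5 minus that at E14.5, adjusted p = 1.03e-09, and adjusted p = 0.409 with an estimated correlation), with medians between 0.54 and 1.54 when each library was left out in turn. The cKO effect was -1.28 at E14.5 and -0.13 at E16.5. Among the 3 WT libraries of E14.5 alone the list median ranged over 1.98 on the log2 scale, and among the 3 cKO libraries over 1.49, a range larger than the difference between the groups, which is consistent with an uneven amount of ventral tissue between dissections. Without WT B the list median was -0.58 and still passed with the preset correlation (adjusted p = 0.0266), though such list calls carry little weight here. That median lay between the limits set for this test, so it does not decide whether ventral tissue in that library alone made the difference. The median of WT A (-1.01 relative to the WT mean) lay below those of cKO B (-0.66) and cKO C (-0.70). An effect of Ash2l loss on ventral genes or on interneurons entering the cortex may also contribute, and these libraries do not separate it from dissection.

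Meningeal fibroblast markers differed by -1.75 (adjusted p = 1.38e-07, and adjusted p = 0.409 with an estimated correlation), with -0.63 as the value nearest to 0 when each library was left out, the one without E14.5 cKO A. Red blood cell markers differed by -0.77 (adjusted p = 2.33e-05, and adjusted p = 0.409 with an estimated correlation), and the call was lost without E14.5 cKO A, at -0.31. The p53 target genes differed by 0.21 (adjusted p = 2.03e-04, and adjusted p = 0.392 with an estimated correlation), and with embryo sex as a term the adjusted p was 0.251. Mitochondrially encoded genes differed by -0.18 (adjusted p = 0.0449, and adjusted p = 0.940 with an estimated correlation), and the call held in 5 of 12 fits with a library left out, with medians between -0.47 and 0.02. It was lost without WT B, cKO B or cKO C of E14.5, and without cKO A, WT B, cKO B or WT C of E16.5. Ribosomal protein genes differed by -0.10 (adjusted p = 3.55e-11, and adjusted p = 0.437 with an estimated correlation). Sex-linked genes differed by 9.12 (adjusted p = 3.29e-06, and adjusted p = 0.190 with an estimated correlation), and with embryo sex as a term the adjusted p was 0.876, and with the block for the shared number 0.0671.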

How the results depend on the processing

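Leaving out libraries leaves an arm with fewer samples, so lost calls there may come in part from fewer samples, a share that was not tested. Counts also rose in some of these fits. They went from 297 to 621 without WT B and cKO A of E14.5, and from 2358 to 2855 without cKO A of E16.5. At the stricter thresholds lost calls come from the threshold itself. For the other changes the cause was not tested. Fits with sex in 12 libraries, pairs of libraries left out, ribosomal RNA removed, the WT libraries alone and the overlap's libraries left out were added after the data were examined.

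At E14.5 the 297 genes (52 higher, 245 lower) were 1187 (253, 934) with DESeq2, 1336 (331, 1005) in the 12-library fit, 128 (24, 104) with sex in that fit, 6 (1, 5) at an adjusted p of 0.01, 152 (21, 131) with a 2-fold limit, and 621 (96, 525) without WT B and cKO A. Leaving out each library in turn gave 5 genes (1 higher, 4 lower) to 3.5e+02 genes (56 higher, 298 lower). Other scalings, filters, limma-voom, no genes on X and Y and no ribosomal RNA gave 281 to 356. Ash2l missed the threshold of 0.01 (-1.28, adjusted p = 0.0124), and with each library left out its change ran from -1.39 to -1.20. The 5 lists were 1 with an estimated correlation and 6 to 12 with a library left out. Reversed values at E14.5 were Xist (-0.29), Ddx3y (3.0) and Uty (1.53) with sex in the 12-library fit, where sex and genotype are confounded at this age, and the G1/S list without cKO A (-0.0226, the lowest with a library left out, the highest being 0.36).

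At E16.5 the 2358 genes (889 higher, 1469 lower) were 807 (187, 620) at 0.01, 669 (191, 478) with a 2-fold limit, 1569 (653, 916) with sex in the 12-library fit, 1223 (340, 883) without WT C and cKO C, and 514 higher with sex as a covariate. Leaving out each library in turn gave 987 to 2855 genes, 249 to 1050 higher and 731 to 1805 lower. Other scalings, filters and tools gave 2273 to 2770 (1163 higher and 1328 lower with library totals), and Ash2l passed in every fit (-1.23 to -1.16 with a library left out). The 1 list was 0 with an estimated correlation and 2 to 7 with a library left out.

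The block for the shared number gave 4790 genes (2132, 2658) and 4 lists at E16.5, 1 gene for the age difference and 1154 shared genes. At E16.5 it ended no call of a named gene or, by camera, of a list, and added those of 7 genes and 3 lists. By fry it ended the calls of pan-neuronal markers (adjusted p = 0.123) and of deep-layer and subplate markers (adjusted p = 0.223). At E14.5 the same-numbered libraries correlated at 0.27 (A), 0.30 (B) and -0.00 (C). The mean for other numbers was -0.097, which the use of deviations from group means itself pushes below 0. Of 6 libraries 4 correlated best with their own number. Not every pair passed the limit of 0.1, so whether the numbers pair the libraries at this age is left open. The block gave 1279 genes (226, 1053) and 7 lists there. It added upper-layer markers (-0.40, adjusted p = 0.00780) and G2/M genes (0.20, adjusted p = 0.0122), each with an adjusted p of 0.941 with an estimated correlation.

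The age difference stayed at 0 genes in each fit with a library left out. The 330 WT age genes were 1967 with DESeq2, 9 at 0.01, 1586 in the 6 WT libraries alone, and 1 to 2216 with a library left out. The 261 shared genes were 1 at 0.01, 967 with DESeq2, and 0 to 302 with a library left out. Of values for named called genes, 350 of 474 at E14.5 kept direction and call, 121 kept direction only and 3 reversed. At E16.5 1137 of 1500 kept both and 363 direction only, and for WT age 99 of 170 and 71.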

Other observations

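The tests of embryo sex, of an equal loss of neurons and of other splits of the libraries were chosen after the results were seen, and the test of exon length and GC content was written before its result was seen.

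Called genes of either direction had a greater total exon length than uncalled genes at both ages. Those lower in cKO had the greatest median length and the most GC-rich transcripts. At E16.5 the median total exon length per gene was 3433 bases for lower, 3219 for higher and 2804 for uncalled genes, and the median GC content was 53.1%, 50.0% and 50.5%. At E14.5 the medians were 3583, 3242 and 2862 bases, and 53.9%, 49.3% and 50.7%. At E16.5 the 109 higher genes with a WT mean under 1 CPM stood against 85 lower genes with a cKO mean under 1 CPM, and at E14.5 the counts were 7 and 14.

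Embryo sex is a candidate explanation for the calls at E14.5, where the cKO libraries were female and the WT libraries male. At E16.5, where both genotypes held both sexes, the female-minus-male coefficient was set against the E14.5 fold change. For the 281 called genes outside X and Y the median ratio was -0.0713 (quartiles -0.165 and 0.0126), while the ratio of the E16.5 genotype effect was 0.980 (quartiles 0.809 and 1.18), which argues against sex as their cause if sex acts alike at both ages. For the 11 called genes on X other than Xist the median sex ratio was 0.122 (quartiles -0.0716 and 0.269) and the genotype ratio 0.762, which argues against sex as the cause for them as a set on the same condition, while it stays open for single genes such as Kdm6a. For Xist and the 4 Y-linked genes the genotype effect at E16.5 was at most 0.0525 of the E14.5 change in size (Eif2s3y). Embryo sex was read from these same genes, so this is no separate test of sex. It shows only that at E16.5, where both genotypes held both sexes by these counts, their levels did not follow genotype. A difference tied to the shared number is balanced between the genotypes, and the block for it gave 1279 genes at E14.5. A difference of stage between single embryos was not tested.

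The lower pan-neuronal genes at E16.5 may reflect fewer neurons, lower transcription in each neuron, or later differentiation. An equal loss of all neurons alone would give the 20 genes 1 fold change only if neurons were the sole source of each RNA. The genes did not share 1 fold change: they spread from -1.80 (Nefl) to 0.20 (Neurod1), with a heterogeneity Q of 9.94 per degree of freedom (19 degrees of freedom). Bulk RNA does not show how much of each RNA came from other cells, so this spread does not decide whether neurons were lost equally. A trend with exon length and GC content does not account for the list, whose median was -0.50 before and -0.42 after the trend was removed, and -0.51 before and -0.42 after in the fit with the block. Cell loss, changes inside cells and a mixture of both stay open, since bulk RNA does not separate them.

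Other splits of the 6 libraries of an age into 3 and 3 number 10, too few for a share under 0.05. At E14.5 the real split called 297 genes and the highest other 1, and 1 of 10 splits was as large as the real one. At E16.5 the real split called 2358 genes and the highest other 1, again 1 of 10, and the splits that part all 3 pairs gave 0 besides the real one. For WT E16.5 against E14.5 the real split called 330 genes and the highest other 0, also 1 of 10. For gene lists 10 of 10 splits called as many as the real one at both ages: 5 real and 18 the highest other at E14.5, and 1 real and 16 the highest other at E16.5. List calls with the preset correlation therefore carry little weight here. For the age difference the real count was 0, which every draw reaches (100 of 100), so this test says nothing about chance. Of the 11 draws that called any gene 10 called 1, and 1 called 1507. That draw kept the E16.5 genotypes and mixed those of E14.5, so the genotype effect at E16.5 stands in its contrast, a structure of the samples. Other draws of that kind called at most 1 gene, so why this draw called so many was not settled.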
